A study of Homo sapiens with 2 samples.

How the data were processed

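HK-2 cells grown with 10% fetal bovine serum were infected for 24 h with an adenovirus carrying either the Bmal1 coding sequence or green fluorescent protein, per the labels. The labels name the line HK-2 for both libraries but spell that name out as human kidney 2 for the library labelled Ad-GFP and human kidney 3 for the other, and both were taken as the same line without a check. Libraries from polyadenylated RNA were sequenced as paired reads of 150 bp, per the labels' protocols. The labels give 2 libraries, 1 per group, and groups were taken from the sample titles. The deposited values are raw counts per gene with Ensembl identifiers, which the authors had not normalised as far as the whole-number values show. Reads were aligned with HISAT2 to GRCh38 (hg38), per the submitters' processing notes. The counting tool, its strand setting and the annotation are not given in the sources used here, so overlapping and antisense genes cannot be separated. The number of unused columns of per-sample values was 0. The numbers in the column headers are not in the labels and were not used.

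Counts were scaled with TMM in edgeR 4.0.16 under R 4.3.3, which gave factors of 1.01 for the library labelled Ad-GFP and 0.988 for the library labelled Ad-Bmal1. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. With 1 library per group no residual degrees of freedom remain, so edgeR's quasi-likelihood test could not be fitted and no p-value or SD is given. The ratio of each gene, library labelled Ad-Bmal1 over library labelled Ad-GFP, has an exact 95% conditional binomial (Clopper-Pearson) interval. Intervals and floors cover counting error only and leave out variation between cultures. Reads without molecular identifiers are not independent molecules, so even counting error may be understated.

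A gene was measured if it reached 1 CPM in at least 1 library, which left 13231 of the 22827 genes with a count. A gene met the size rule if it was measured, differed by at least 2-fold and had an interval that excluded 1. A count of 0 was set to a floor of 3 counts, or 0.148 CPM in the library labelled Ad-GFP and 0.151 in the other. For each of 31 gene lists the median log2 ratio of measured members was placed as a percentile among 10000 random lists of equal size, matched on mean expression in 50 bins. A percentile under 2.5 or over 97.5 is outside the 95% range. This describes the libraries and is no test of the conditions.

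The comparison, the size rule, the lists and the genes to name were chosen before the data were examined. Named genes are BMAL1, every measured core clock gene, and the 12 genes per direction whose interval bound lay farthest from 1 among those that met the size rule and had a symbol that is no placeholder or pseudogene. Each list adds up to 4 members that met the size rule, or, where none did, up to 2 with the highest mean count. The values of some genes this rule names are not reported here. Any other gene named, in the report or in the closing parts, was chosen after its values were seen, except NFIL3. Coordinates and transcript lengths are from GENCODE v29 on GRCh38, which held 99.5% of the 58302 gene identifiers in the table. The length is that of the gene's longest annotated transcript, a coding one where there is any, which need not be the one expressed in these cells. Where the length trend was removed, genes without a length were given the median length.

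The steps were tested on simulated counts with 200 changed genes drawn at the real depth. With counting noise alone the size rule found 95.5% of genes changed 2.5-fold and 2.5% of those changed 1.5-fold, and it called 38 to 43 unchanged genes. With an assumed 10% variation between cultures it called 76 to 85 unchanged genes, and with 20% it called 438 to 445. Of 200 simulated unchanged lists of 25 genes, with counting noise alone and no matching on expression, 4.0% lay outside the 95% range. Adding 0.5 on the log2 scale to their medians put 100.0% above it. That shift is larger than any list median reported here, and smaller shifts were not tested.

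Alternatives were total counts, DESeq2 1.42.0 size factors, upper-quartile scaling, and totals without mitochondrial and the 20 most abundant genes. Others were no filter, a filter of 10 CPM, sizes of 1.5-fold and 4-fold, an interval wholly beyond 2-fold, thinning the deeper library to the total of the other, which differed by little, a prior count of 2 and unmatched random lists. Removal of the length trend, protein-coding genes alone and length-matched random lists were added after seeing the data.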

Results

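Gene expression was measured by RNA sequencing in HK-2 cells, an immortalised line from the proximal tubule of human kidney. The cells had been infected for 24 h with an adenovirus, a vector that carries a gene into cells without integrating it. One vector carried the coding sequence of Bmal1, the transcription factor that pairs with CLOCK to drive the circadian clock, and the control vector carried green fluorescent protein. There was 1 library per group, so no difference below has a replicate check, and each describes these 2 libraries rather than the conditions. The library labelled Ad-GFP held 20032652 counts over 20709 genes and the library labelled Ad-Bmal1 held 20051735 counts over 20780 genes. At this depth 1 CPM (a count scaled to library size) was worth 20.3 counts in the former and 19.8 in the latter. The series title places the comparison in work on Bmal1, cisplatin injury of the kidney and a liver-like state of kidney tissue. No library here was labelled as treated with cisplatin.

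BMAL1, the gene the vector was meant to raise (ENSG00000133794, chromosome 11, 13276652 to 13387266, GRCh38), had 204 counts in the library labelled Ad-GFP and 133 in the library labelled Ad-Bmal1. Its scaled level in the latter was 0.667 times that in the former (95% counting interval 0.532 to 0.834). The targeted gene therefore went against the label, and every direction below is given for the library labelled Ad-Bmal1 with that limit. The deposited counts cannot tell transcripts of the vector from those of the cell's own gene.

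Among the core clock genes the period genes and NR1D1 were higher in the library labelled Ad-Bmal1, while the activators BMAL1, NPAS2 and BMAL2 were lower. NR1D1, which encodes the repressor REV-ERB alpha, had 131 and 319 counts in the libraries labelled Ad-GFP and Ad-Bmal1 (2.49-fold higher, interval 2.03 to 3.08, chromosome 17, 40092787 to 40100725). PER1, a negative regulator of the CLOCK and BMAL1 pair, was 1.85-fold higher (1.65 to 2.07), PER2 1.68-fold (1.24 to 2.28) and PER3 1.39-fold (1.12 to 1.74). BHLHE41, another repressor of the clock, was 1.42-fold higher (1.26 to 1.60) and TIMELESS 1.24-fold (1.18 to 1.31). NPAS2, a partner of BMAL1 that can take the place of CLOCK, had 73 and 46 counts, a ratio of 0.645 (0.436 to 0.945), and the BMAL1 paralog BMAL2 had a ratio of 0.702 (0.587 to 0.837).

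Of the 19 measured core clock genes 1 met the size rule, NR1D1, and the list median was -0.16 on the log2 scale, at percentile 3.24 of random lists. The kinases that mark period proteins for turnover differed in direction, with ratios of 1.12 (1.07 to 1.17) for CSNK1D and 0.760 (0.708 to 0.815) for CSNK1E. The repressor genes CRY1 and BHLHE40 had ratios of 0.830 (0.710 to 0.970) and 0.879 (0.830 to 0.931). The intervals of CLOCK (0.826, 0.537 to 1.27), CRY2 (0.896, 0.749 to 1.07), NR1D2 (1.17, 0.914 to 1.5), RORA (0.737, 0.379 to 1.41) and CIART (0.927, 0.706 to 1.22) included 1. Against random lists matched also on transcript length, the core clock median lay at percentile 1.23.

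Genes that BMAL1 and CLOCK bind through E-box elements were higher as a list in the library labelled Ad-Bmal1, with a median log2 ratio of 0.24 over 19 measured members at percentile 99.71. Of these 11 had ratios above 1 and 8 below, with 10 intervals above 1 and 3 below. NR1D1 and DBP met the size rule and none was lower by it. DBP, a transcription factor whose promoter carries E-boxes, had 95 and 216 counts, 2.33-fold higher (1.82 to 2.99, chromosome 19, 48630030 to 48637438). The list shares 11 genes with the core clock list, and of the 9 measured members outside that list 5 had a ratio above 1 and 4 below.

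**Figure D1:**
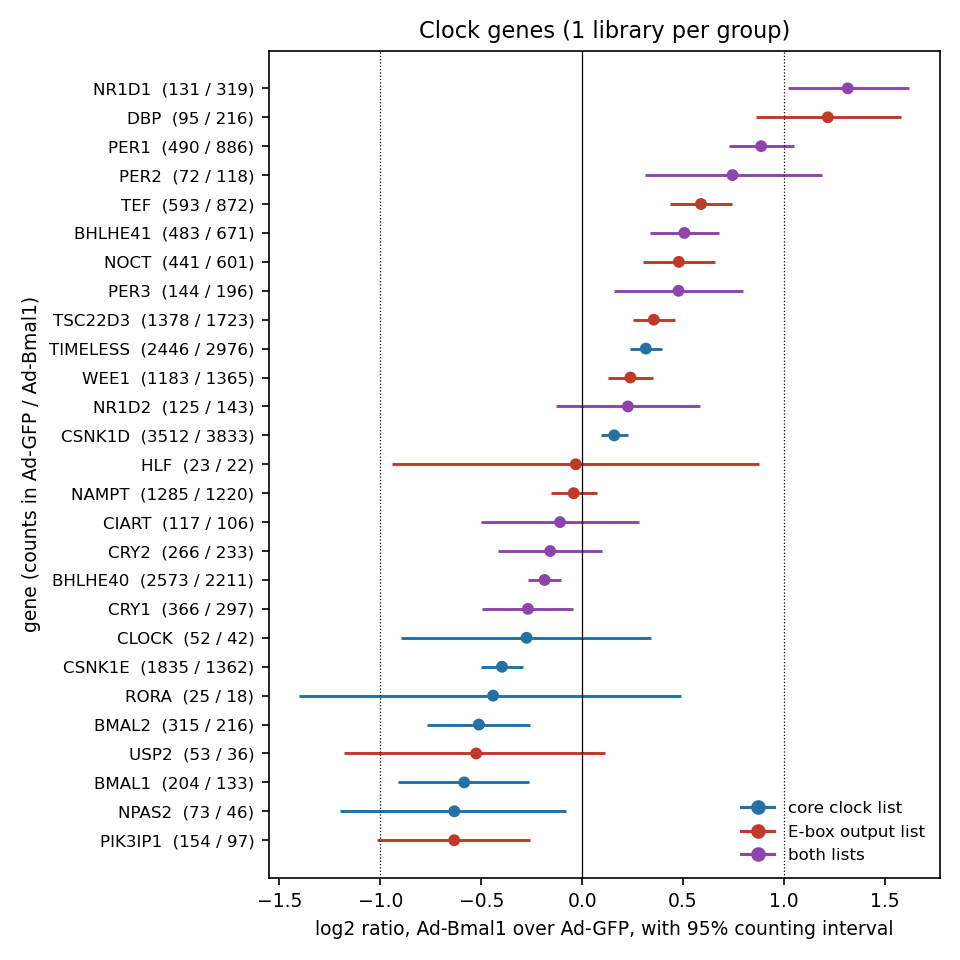
Log2 ratio of measured core clock and E-box output genes (horizontal axis), library labelled Ad-Bmal1 over library labelled Ad-GFP, with 95% counting intervals as bars and counts of both libraries beside each symbol. NR1D1 and DBP lie beyond the dotted 2-fold line on the right, and BMAL1, at 204 and 133 counts, lies to the left of 0.

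Across the transcriptome, 149 genes were higher and 230 lower in the library labelled Ad-Bmal1 by the size rule, of 13231 measured. Most were of low abundance, with 110 of the higher and 178 of the lower genes under 100 counts in both libraries. The log2 CPM of the libraries had a Pearson r of 0.986 across genes, which are not independent replicates. Of 5658 genes with 1000 or more counts in all, 96.2% had ratios within 1.5-fold. On simulated counts with an assumed 20% variation between cultures, 438 to 445 unchanged genes met the size rule, more than met it in the real libraries. With an assumed 10% variation 76 to 85 did, fewer than in the real libraries. Over the 5658 genes with 1000 or more counts, the scaled median absolute deviation of the real log2 ratios was 0.226. Neither setting was fitted to that spread, and the real variation between cultures is unknown with 1 library per group. An unknown share of the genes that met the rule therefore need not reflect the vectors. The direction is again that of labels which BMAL1 did not bear out.

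**Figure D2:**
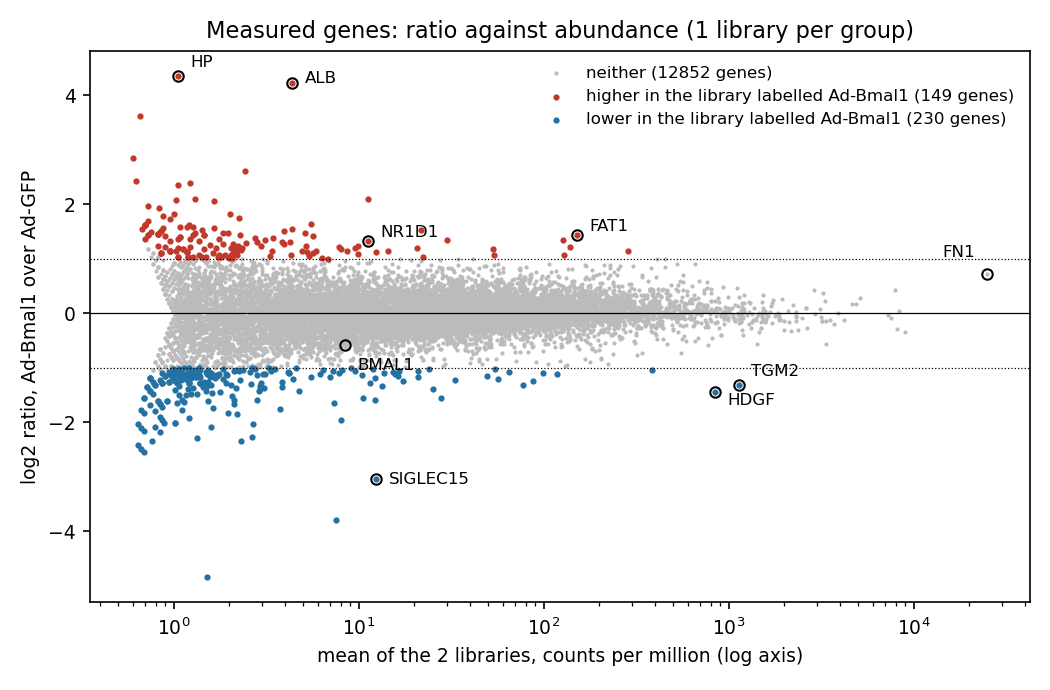
Log2 ratio of each measured gene (vertical axis), library labelled Ad-Bmal1 over library labelled Ad-GFP, against its mean CPM (log axis). Red points are the 149 genes higher and blue points the 230 genes lower by the size rule, and most lie at low abundance.

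The genes with the firmest excess in the library labelled Ad-Bmal1 included ALB, HP and AMBP at low counts and FAT1, CRISPLD2 and MAPK8IP2 at high counts. ALB, which encodes serum albumin, had 9 and 165 counts (18.8-fold, interval 9.64 to 41.8, chromosome 4, 73397114 to 73421412). HP, which encodes the haemoglobin-binding protein haptoglobin, had 2 and 40 counts (ratio 20.5, 5.31 to 175), and AMBP, the precursor of alpha-1-microglobulin and bikunin, had 13 and 53 (4.17-fold, 2.24 to 8.34). FAT1, an atypical cadherin, had 1651 and 4353 counts (2.70-fold, 2.55 to 2.86, chromosome 4, 186587783 to 186726722), and CRISPLD2, a secreted glycoprotein gene, 1463 and 3624 (2.53-fold, 2.38 to 2.70).

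EPPK1, the cytoskeletal linker epiplakin, was 4.27-fold higher (3.37 to 5.46). MAPK8IP2, a scaffold of JNK signalling, was 2.32-fold higher (2.19 to 2.46), FRMPD3 2.53-fold (2.23 to 2.88) and MAB21L3 3.09-fold (2.26 to 4.27). PRODH, a mitochondrial enzyme of proline breakdown, had 2 and 24 counts (ratio 12.3, 3.05 to 107). KCNJ14, an inward-rectifier potassium channel gene, had 8 and 41 (5.24-fold, 2.43 to 13.0), and C21orf91 had 3 and 21 (ratio 7.16, 2.14 to 37.5).

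The genes with the firmest deficit in the library labelled Ad-Bmal1 included SIGLEC15, TGM2, HDGF and MMP1. SIGLEC15, a sialic acid-binding receptor known from osteoclasts and macrophages, had 450 and 53 counts, 8.30-fold lower (6.23 to 11.3, chromosome 18, 45825512 to 45844080). TGM2, the protein-crosslinking enzyme transglutaminase 2, had 32779 and 12889 counts, 2.49-fold lower (2.44 to 2.54, chromosome 20, 38127387 to 38166578). HDGF, a heparin-binding growth factor gene, had 25119 and 8953 counts, 2.74-fold lower (2.68 to 2.81, chromosome 1, 156742107 to 156766925). MMP1, interstitial collagenase, was 2.5-fold lower (2.31 to 2.70).

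LAPTM5, a lysosomal protein gene mainly known from blood cells, was 3.88-fold lower (2.95 to 5.17), and CFP, the complement regulator properdin, 4.89-fold (2.36 to 11.4). CSF3, which encodes granulocyte colony-stimulating factor, was 4.83-fold lower (2.89 to 8.52), PI3, the elastase inhibitor elafin, 4.10-fold (2.52 to 6.94) and DDIT4L, a relative of the mTOR inhibitor DDIT4, 5.08-fold (2.90 to 9.51). CEMIP2, a cell surface hyaluronidase gene, was 3.04-fold lower (2.47 to 3.76) and COMMD1, which acts in copper handling, 2.93-fold (2.35 to 3.68). CBS, an enzyme of homocysteine metabolism, was 2.94-fold lower (2.56 to 3.38), but its near-identical copy CBSL went the other way with 157 and 239 counts. The ratio of the summed counts of CBS and CBSL was 0.532 (0.477 to 0.592), so the size of the CBS difference is uncertain.

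Genes of hepatocyte plasma proteins were mostly at trace level, with 12 of 58 listed genes measured. Of these 3 met the size rule as higher in the library labelled Ad-Bmal1, ALB, HP and AMBP, and none as lower. Each of the 3 was under 1 CPM in the library labelled Ad-GFP and was measured only through the other library. Intervals of 4 members lay above 1, with C3 at 1.26 (1.24 to 1.29) the fourth. Those of 2 lay below 1, SAA1 at 0.673 (0.619 to 0.731) and SERPINA1 at 0.855 (0.823 to 0.8875). The list median of 0.13 lay at percentile 89.2, within the range of random lists. Under a minimum of 10 CPM, which leaves out those 3 genes, the median was -0.04.

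**Figure D3:**
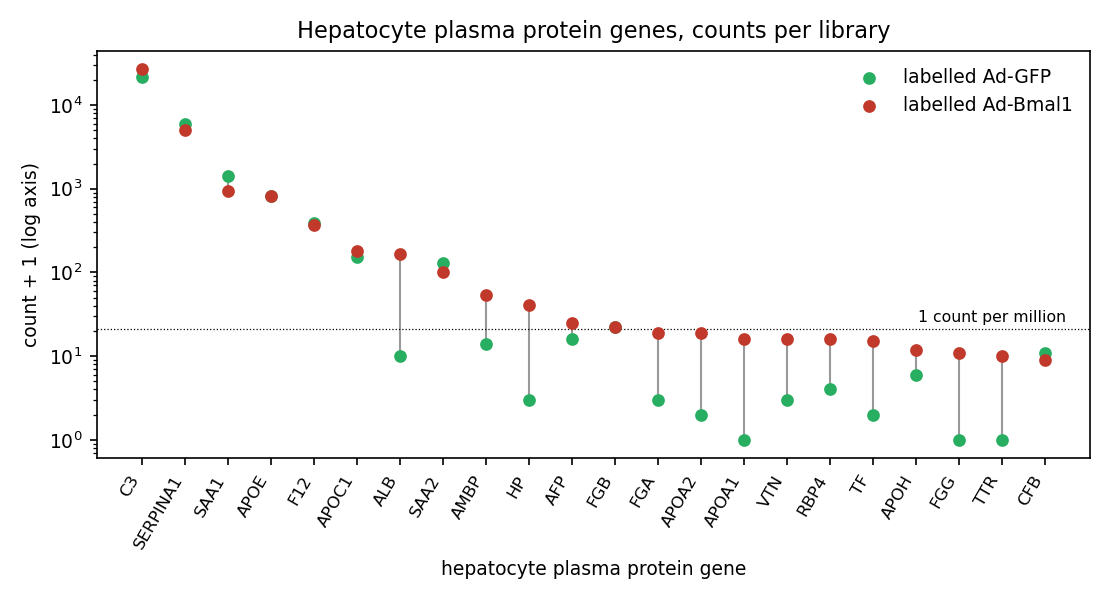
Counts plus 1 (log axis) of hepatocyte plasma protein genes with at least 9 counts in 1 library, for the libraries labelled Ad-GFP (green) and Ad-Bmal1 (red). ALB, at 9 and 165 counts, stands apart from APOE and F12, whose points nearly coincide. Genes with both points under the dotted line at 1 CPM were not measured, and most of them reached 9 counts only in the library labelled Ad-Bmal1.

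Other hepatic lists held few genes that met the size rule. Among 15 measured liver-enriched transcription factors, ONECUT2 had 24 and 48 counts (2.05-fold higher in the library labelled Ad-Bmal1, 1.23 to 3.49). That ratio was 1.998 under total counts and 1.68 with a trend on transcript length removed, so ONECUT2 did not meet the rule under either. The list median was 0.12 at percentile 86.5, and -0.09 over the 5 members that reached 10 CPM. Among 9 genes of xenobiotic and bile acid metabolism the median was -0.21 at percentile 4.69, and GSTA1, a glutathione transferase, had 34 and 16 counts. GSTA1 is uncertain, because its sum with the close paralog GSTA2 had a ratio of 0.841 (0.610 to 1.16). Among 11 genes of nitrogen, amino acid and glucose metabolism the median was 0.01 at percentile 51.8, and -0.02 under total counts. KHK, the fructose-phosphorylating enzyme, was 2.04-fold lower (1.42 to 2.97), but its ratio was 0.5035 with the length trend removed, outside the rule.

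In the kidney lists 1 measured gene met the size rule. Among 16 proximal tubule genes this was PDZK1, a scaffold of apical transporters, 2.27-fold lower in the library labelled Ad-Bmal1 (1.87 to 2.77). The list median was nevertheless 0.17, at percentile 96.9, and at 98.9 when random lists were matched also on length. Of 15 genes of cisplatin and copper transport none met the rule, and 7 had intervals below 1 against 5 above. The median was 0.08 at percentile 82.0, but -0.15 over the 13 members that reached 10 CPM, and GSTP1, a glutathione transferase, had a ratio of 0.879 (0.863 to 0.895). The 24 tubular injury genes had a median of -0.12 at percentile 0.47, with none meeting the rule, and at percentile 4.66 without matching on expression. SPP1, which encodes osteopontin, had a ratio of 0.878 (0.865 to 0.891) and S100A6, a calcium-binding protein gene, 0.927 (0.912 to 0.941).

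Inflammatory genes under NF-kB control were lower as a list in the library labelled Ad-Bmal1, with 22 of 27 members below a ratio of 1. Their median was -0.17, at percentile 0.06. CSF3 met the size rule, as did CD83, an immune surface protein gene with 1606 and 683 counts (2.30-fold lower, 2.10 to 2.52), and CXCL3, a neutrophil chemokine gene (2.10-fold lower, 1.69 to 2.62). The ratio of the summed counts of CXCL3 and its close paralog CXCL2 was 0.845 (0.790 to 0.903), so CXCL3 is uncertain. Interferon-stimulated genes had a median of -0.07 at percentile 19.6 over 29 members. IFITM1, a restriction factor against virus entry, was 2.44-fold lower (1.47 to 4.21) and CMPK2, a mitochondrial nucleotide kinase, 2.20-fold (1.08 to 4.77).

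Hypoxia and glycolysis genes were lower as a list, with 23 of 33 members below a ratio of 1, a median of -0.16 and a percentile of 0.00, meaning that none of 10000 random lists lay lower. No member met the size rule, and the glycolytic enzyme genes ENO1 and PGK1 had ratios of 0.973 (0.966 to 0.981) and 0.905 (0.895 to 0.915). With the length trend removed these were 1.003 and 0.8655, so the direction of ENO1 is uncertain. The metallothionein list had a median of -0.44 at percentile 0.01 over 8 measured genes, with 7 below a ratio of 1. MT2A and MT1E, metal-binding protein genes, had ratios of 0.796 (0.785 to 0.807) and 0.701 (0.683 to 0.719). Reads may be split between such similar genes, and the summed counts of this pair had a ratio of 0.775 (0.765 to 0.784).

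Cholesterol and lipid synthesis genes were higher as a list in the library labelled Ad-Bmal1, with 22 of 28 members above a ratio of 1 and a median of 0.19 at percentile 99.76. SCD, which introduces a double bond into fatty acids, had 9235 and 16890 counts, a ratio of 1.87 (1.82 to 1.92). Extracellular matrix and TGF-beta response genes had a median of 0.21 at percentile 99.93, although MMP1, the member that met the size rule, was lower. That percentile was 96.1 when random lists were matched also on transcript length. The fibroblast and smooth muscle markers, which share 3 genes with this list, were shifted the same way, with a median of 0.42 at percentile 98.5. FN1, which encodes fibronectin and belongs to this list, had 382264 and 614596 counts, a ratio of 1.65 (1.64 to 1.65).

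Several stress and growth lists held no or 1 gene that met the size rule. The 28 p53 targets had a median of 0.13 at percentile 97.7, and 97.3 without matching on expression, with ratios of 0.930 (0.903 to 0.959) for the kinase gene PLK2 and 0.935 (0.901 to 0.969) for the stress cytokine GDF15. The 18 heat shock genes had a median of 0.17 at percentile 98.4, and 97.2 without matching, with ratios of 1.11 (1.10 to 1.13) for the chaperone HSP90AB1 and 1.14 (1.12 to 1.16) for HSPB1. SLC7A11, the cystine transporter, had 27 and 62 counts (2.35-fold higher, 1.47 to 3.84) and is a member of both the unfolded protein list (median 0.07, percentile 84.1) and the NRF2 list (0.09, 90.4). Among 25 apoptosis regulators BCL2A1, an anti-apoptotic gene, was 2.59-fold lower (1.73 to 3.96), with a median of -0.06 at percentile 13.8.

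Proliferation lists showed no shift beyond random lists, with medians of -0.02 at percentile 14.6 for 30 S-phase genes and 0.00 at percentile 38.4 for 30 mitosis genes, the latter -0.03 under total counts. The replication helicase gene MCM7 had a ratio of 1.03 (1.00 to 1.05), thymidine kinase TK1 1.09 (1.07 to 1.12), the spindle factor TPX2 1.10 (1.06 to 1.13) and CDC20, an activator of mitotic exit, 1.00 (0.969 to 1.04), which lay on the other side of 1 under each other scaling. Immediate early genes had a median of -0.01 at percentile 39.1, with FOSL2, an AP-1 subunit, at 1.03 (1.00 to 1.05) and IER3 at 1.28 (1.25 to 1.32). With the length trend removed FOSL2 was at 0.936, on the other side of 1, and IER3 at 1.36. The epithelial and mesenchymal list had a median of -0.12 at percentile 2.79, with 5 intervals above 1 and 8 below. Its most abundant members went opposite ways, with ratios of 1.65 (1.64 to 1.65) for FN1 and 0.953 (0.935 to 0.972) for the keratin gene KRT8. The 6 measured aryl hydrocarbon receptor targets had a median of 0.10 at percentile 74.7, with NQO1, a quinone reductase, at 0.850 (0.809 to 0.893) and ARNT, the receptor's partner, at 1.20 (1.09 to 1.33).

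Among markers of other cell types, distal nephron genes had 3 measured members of 17 listed and a median of 0.17 at percentile 67.1, with intervals that included 1 for HSD11B2 (1.59, 0.876 to 2.94) and SCNN1A (1.13, 0.586 to 2.17). Podocyte and endothelial genes had 4 and a median of -0.19 at percentile 26.96, or 0.03 for the 1 member that reached 10 CPM, with TIE1, an endothelial receptor gene, at 28 and 7 counts (3.91-fold lower, 1.67 to 10.6). CSF1R, the receptor of macrophage colony-stimulating factor, was the single measured blood cell marker, at 0.962 (0.838 to 1.10) and percentile 42.4. The fibroblast and smooth muscle list had 7 measured members of 13, 6 of them above a ratio of 1, and a median of 0.42 at percentile 98.5, and THY1, a surface glycoprotein gene, had 8 and 33 counts (4.22-fold higher, 1.91 to 10.6).

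Messenger RNAs of the mitochondrial genome had ratios above 1 for 13 of 13 genes under TMM scaling and for 12 of 13 under each of the 4 other scalings. The interval lay above 1 for 11 of them under TMM scaling, and the median was 0.23 at percentile 99.86. MT-CO1 and MT-CO2, subunits of cytochrome oxidase, had ratios of 1.13 (1.12 to 1.14) and 1.06 (1.05 to 1.08). The mitochondrial genome took 1.52% of counts in the library labelled Ad-GFP and 1.73% in the other. This list was included as a sign of RNA quality, and whether its shift bears on those of the other lists was not tested. Housekeeping genes had a median of -0.06 at percentile 9.27, with ratios of 0.791 (0.786 to 0.796) for the elongation factor EEF1A1 and 0.815 (0.809 to 0.820) for ACTB, beta-actin. Of the 31 lists, 4 lay below and 7 above the 95% range of random lists, against 1.55 expected by chance, and random lists leave out the co-regulation of real list members.

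**Figure D4:**
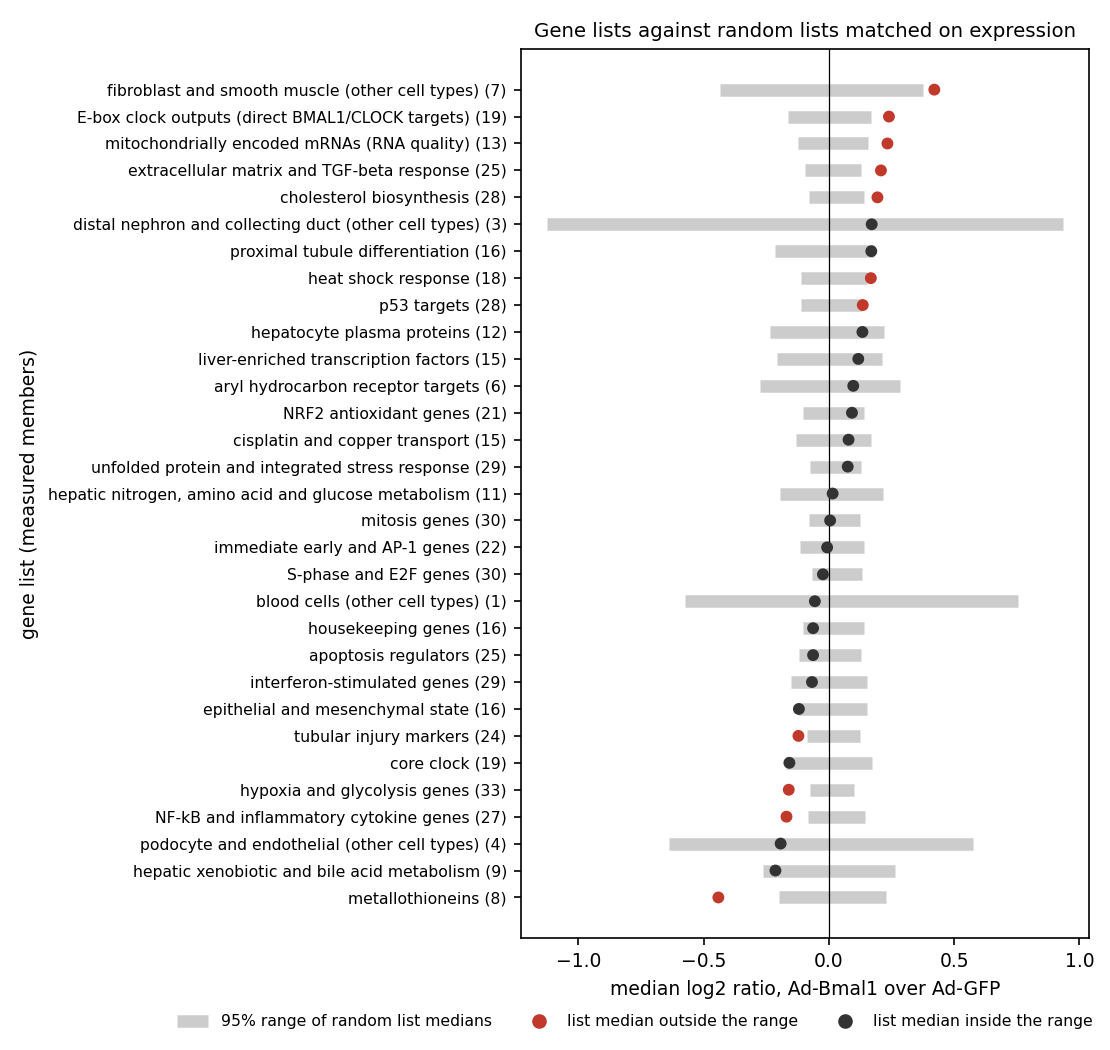
Median log2 ratio (horizontal axis) of the measured members of each gene list, library labelled Ad-Bmal1 over library labelled Ad-GFP, with the 95% range of medians of expression-matched random lists as grey bars and the number of members in brackets. Metallothioneins lie farthest to the left at -0.44 and fibroblast and smooth muscle genes farthest to the right at 0.42.

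Ratios were also related to transcript length. Over 9393 protein-coding genes with at least 200 counts, Spearman's rho of the log2 ratio was 0.307 with transcript length, 0.207 with the gene's span in the genome and -0.03 with GC content, all across genes, which are not replicates. The median log2 ratio went from -0.08 in the 10% of genes with the shortest transcripts to 0.21 in the 10% with the longest, where 12 genes were higher and 0 lower by the size rule. With the trend removed, the ratios were 2.24 in place of 2.70 for FAT1, 3.52 in place of 4.27 for EPPK1, 1.43 in place of 1.65 for FN1 and 19.4 in place of 18.8 for ALB. GSTA1 and CXCL3 no longer differed by 2-fold, at 0.510 and 0.5045.

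**Figure D5:**
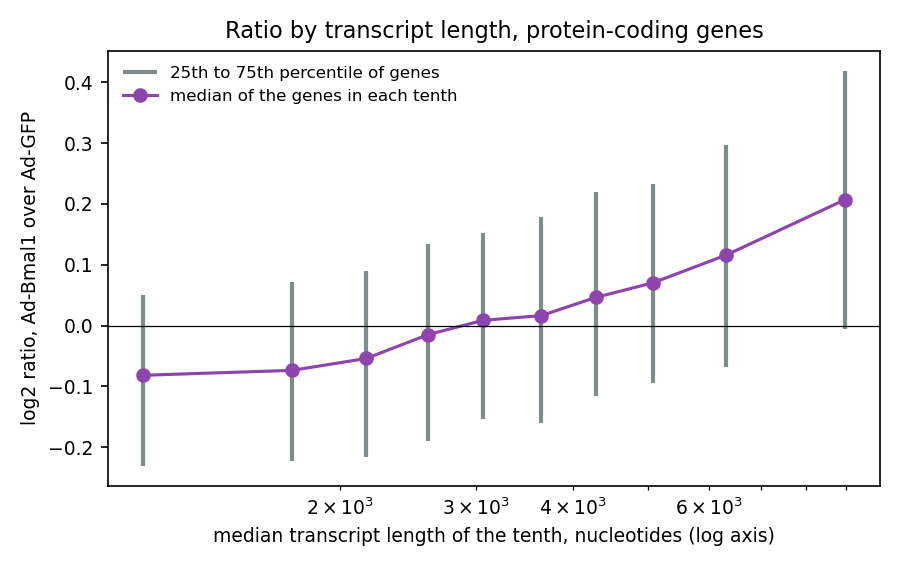
Median log2 ratio (points), library labelled Ad-Bmal1 over library labelled Ad-GFP, with the 25th to 75th percentile of genes (bars) in 10 equal groups of protein-coding genes by transcript length (log axis, nucleotides). The median goes from -0.08 in the shortest group to 0.21 in the longest.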

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

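All tests in this part were chosen after the result was seen. Hepatocyte plasma protein genes that stayed under 1 CPM in both libraries, and so entered no comparison above, had more counts in the library labelled Ad-Bmal1 than in the library labelled Ad-GFP. Over 37 genes the counts were 59 in the library labelled Ad-GFP and 208 in the library labelled Ad-Bmal1, a pooled ratio of 3.61 (95% counting interval 2.69 to 4.90), with 29 genes higher in the latter and 6 in the former. Among them, named after their values were seen, the apolipoprotein genes APOA2 and APOA1 had 1 and 18 counts and 0 and 15 counts. The fibrinogen chain genes FGA and FGG had 2 and 18 and 0 and 10, and TTR, which encodes the thyroxine carrier transthyretin, had 0 and 9. Pooled trace counts of the other hepatic lists had ratios of 1.46 (0.702 to 3.13) for liver-enriched transcription factors, 1.31 (0.979 to 1.76) for xenobiotic and bile acid genes and 1.478 (0.948 to 2.33) for nitrogen, amino acid and glucose genes, all above 1 with intervals that included 1. Those of proximal tubule genes (ratio 0.857, 0.610 to 1.20) and of blood cell genes (0.787, 0.417 to 1.47) also had intervals that included 1, as did those of distal nephron (0.921), podocyte and endothelial (1.02) and fibroblast and smooth muscle genes (1.11).

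Against a general gain of counts near the floor, all 9596 genes under 1 CPM had a pooled ratio of 0.973 (0.959 to 0.988), below the interval of the hepatocyte genes. RNA of liver or hepatoma cells may have entered the library labelled Ad-Bmal1, or its reads may have been assigned to it, and this stays open. The fibrinogen chain gene FGB had 21 counts in both libraries, which falls short of the mean gain of FGA and FGG by 1.8 counting standard errors, too little to decide. A gene programme begun in these cells under the liver-enriched transcription factors also stays open. That list lay at percentile 86.5, inside the range of random lists. Only a percentile under 2.5 would have counted against the programme, so a list without a change could not have done so. The list median turned from 0.12 to -0.09 at 10 CPM, and HNF4A, a regulator of hepatocyte genes, had 1 and 0 counts. Neither shows a rise of these factors. With 1 library per group, liver RNA and such a programme cannot be told apart.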

How the results depend on the processing

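Removal of the length trend, protein-coding genes alone and length-matched lists were chosen after seeing the data. The BMAL1 ratio stayed below 1 under 4 other scalings, at 0.651 to 0.665. Those scalings shifted the median log2 ratio of measured genes by only -0.0345 to -0.0052, too little to carry the BMAL1 ratio across 1. The genes higher and lower numbered 129 and 263 under total counts, 142 and 243 under DESeq2 size factors, 145 and 231 under upper quartile scaling, 149 and 231 after thinning to equal totals, which removed few counts, 136 and 226 without the length trend and 113 and 177 among protein-coding genes. They numbered 292 and 399 with no filter, 21 and 38 at 10 CPM, 583 and 648 at 1.5-fold, 12 and 20 at 4-fold, and 23 and 28 with the whole interval beyond 2-fold, each by a wider or narrower rule. Of ratios of named genes under other scalings, 309 stayed within their counting interval and 35 moved out of it, with CDC20 alone changing sides of 1. Of list medians, 176 stayed and 9 moved. Percentiles of tubular injury, p53 and heat shock lists came inside the 95% range without matching, and that of the matrix list with length matching, where those of the core clock and proximal tubule lists went outside it. The distal nephron list had no member at 10 CPM. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible either. Depth limits most genes that met the size rule, since 110 of the higher and 178 of the lower had under 100 counts in both libraries.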

Other observations

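Tests in this part were chosen after the result was seen, except that of NFIL3. Some further genes lower in the library labelled Ad-Bmal1 were picked after their values were seen and stand for no group. LCP1, the actin bundler L-plastin, had 196 and 85 counts (2.25-fold lower, 1.74 to 2.94), and FMNL1, a formin, 495 and 204 (2.37-fold lower, 2.01 to 2.81). NFKBIE, an inhibitor of NF-kB, had 389 and 151 counts (2.52-fold lower, 2.08 to 3.06). TXNIP, an inhibitor of thioredoxin and of glucose uptake, had 2501 and 1037 (2.36-fold lower, 2.19 to 2.54). Of genes with at least 1000 counts in all, 8 met the size rule as higher and 14 as lower. The higher ones include HSPG2, which encodes the basement membrane proteoglycan perlecan (2.21-fold, 2.13 to 2.30), and VCAN, which encodes versican (2.08-fold, 1.90 to 2.28). With the length trend removed their ratios were 1.84 and 1.75, under the size rule. THBS1, which encodes thrombospondin 1, had 5558 and 10835 counts, a ratio of 1.99 (1.93 to 2.06), just under the size rule.

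Some large ratios belong to near-identical copies, chosen after their values were seen. The pseudogene IKBKGP1 had 285 and 20 counts against a ratio of 0.865 (0.729 to 1.03) for its parent IKBKG, and the summed ratio was 0.477 (0.412 to 0.552). MTX1P1 had a ratio of 0.318 and its sum with MTX1 0.940 (0.856 to 1.03). EIF3CL had a ratio of 2.30, EIF3C 0.687 (0.614 to 0.768), and their sum 0.896 (0.814 to 0.986).

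BMAL1 was not higher in the library labelled Ad-Bmal1, although 10 of its 19 measured E-box outputs had intervals above 1, NR1D1, DBP, PER1 and PER2 among them, while 3 had intervals below 1, among them PIK3IP1 with a ratio of 0.645 (0.495 to 0.836). Exchanged labels stay open and the BMAL1 counts do not test them. The limit for the lowest lower bound over the scalings, 0.52, was set after that value was seen. It was then moved from 0.5, which would have excluded an exchange, to 1, which could not. The sign set for an exchange with counted transgene reads was an upper bound of the BMAL1 ratio below 0.5. That sign was not met, with an upper bound of 0.834, but it too was set after the data were seen. Transgene reads may not have been counted on the human gene, for instance if the sequence came from another species, and the upper bound of 0.834 leaves this open because such reads leave no trace in these counts. More REV-ERB alpha may have lowered BMAL1, which it represses, and NFIL3, another gene it represses, had a ratio of 0.900 (0.780 to 1.04), an interval that includes 1. If the labels were exchanged, those 10 E-box outputs would be lower, and those 3 higher, in the library given Bmal1. Uncounted transgene reads and lowering by REV-ERB alpha may hold together, since the latter would show only where transgene reads were few or uncounted. The 3 explanations cannot be told apart without reads of the vector. They are also not a full set, since variation between cultures is unknown with 1 library per group and was not tested as a cause.

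The trend of ratios with transcript length may be technical, such as a difference in RNA integrity or fragment size, or biological, and neither was tested directly. Of the genes that met the size rule 86.0% still met it once the trend was removed. These were 120 of 149 higher and 206 of 230 lower. The median log2 ratio differed by only 0.29 between the groups with the longest and the shortest transcripts, well under 2-fold. Removing the trend could therefore drop mainly genes near the 2-fold line. Whether a technical difference gave single genes large ratios cannot be decided from this count. The span of the gene in the genome as the main driver of the trend is argued against, within these libraries. In a joint fit that also held GC content, its slope was 0.0235 ± 0.0039 (bootstrap SE over genes) per SD, against 0.0822 ± 0.0038 for transcript length. The slope on GC content was 0.0183 ± 0.0031. Genes are not independent replicates, so these SEs may be too small. The extracellular matrix list lay at percentile 96.1 under length matching, inside the 95% range.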
